A study of Triticum monococcum with 54 samples.

How the data were processed

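Whole grain of Triticum monococcum, sampled at 6 stages under up to 4 N and S treatments, was profiled by strand-specific polyadenylated RNA sequencing with paired 125-base reads, per the labels' protocols. The 54 libraries were grouped by stage and treatment from their sample labels, 3 biological replicates to a group as the labels state, and run on 3 sequencing lanes named in the sample descriptions. The stages 100, 200 and 300 °Cd were on the first lane. All libraries of 400 °Cd and the N-S- and N+S- libraries of 500 °Cd were on the second, and the rest of 500 °Cd and all of 600 °Cd on the third. S supply at 500 °Cd is therefore confounded with lane, and so are the steps from 300 to 400 and 500 to 600 °Cd in N-S- grain and every change from 300 to 600 °Cd.

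The authors deposited a table for each treatment with, per the file headers, a raw count and a normalized count per gene and library, the gene's length, and a covered length that is not defined in the sources used here. Per the submitters' processing notes, CASAVA 1.8.4, BWA 0.7.12-r1039 and edgeR (no version) were used, and the reference sequence and the counting tool are not given in the sources used here. The deposited raw counts are whole numbers whose totals differ between libraries, and they were the input to all tests. In each deposited column the normalized signal was the raw count divided by a constant. In each of the 2 complete tables the constants correspond to normalization factors with a geometric mean of 1, so each table was normalized on its own, with factors of 0.772 to 1.53 in N-S- and 0.941 to 1.05 in N+S+. These normalized values were therefore not compared between treatments.

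The tables as used here hold 32047 genes for N-S- and for N+S+, 18308 for N+S- and 8649 complete rows for N-S+, in the same order from TmLoc000002 on. The rest of the 2 shorter tables was not analysed here. The 8649 genes in all 4 tables were used for every main comparison, and library sizes, scaling and counts scaled to library size (CPM) refer to these genes only. Description fields held no text and no annotation was used, so identifiers could not be paired with names. Planned lists of genes by function or cell type could not be tested for that reason, and the camera and fry tests meant for them were not run.

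Library totals over the shared genes ran from 370241 at 400 °Cd to 1736179 at 600 °Cd. No pair of replicates had identical counts, and the closest of the 54 pairs differed by 2.90 times the chi-square expected from sampling alone, so each library was counted as a replicate of its own. Genes were kept with filterByExpr, which left 4001, and scaled by the trimmed mean of M values (TMM). One quasi-likelihood model with a mean per group was fitted to all 54 libraries in edgeR 4.0.16 (R 4.3.3), with a trended dispersion, so every comparison shares an estimate of the spread. Contrasts averaged 300, 400, 500 and 600 °Cd with equal weight or compared single groups. P-values were adjusted by Benjamini-Hochberg over the tested genes, and a gene was called at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic.

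Genes named in the text were chosen by rule: among called genes with a mean of at least 1 CPM and the same sign at each stage (for stage comparisons, in every replicate), the 2 that rose most and the 2 that fell most. The 20 most abundant of the 8649 shared genes over all libraries, and the genes named among them, were chosen after the data had been seen. Shares of counts were compared by two-sided exact permutation tests within stages over 160000 arrangements. Where a group had 0 counts, the fold is a lower bound against 3 counts summed over the group.

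The model was tested on simulated counts for the 4001 genes with 100 genes changed at each of 2 sizes. For N+S- against N+S+ averaged over the stages it called 70% of genes changed by 1 and 85% of those changed by 2 on the log2 scale, with 2.52% false calls. For the same comparison at 600 °Cd it called 24% and 57%, with 4.71% false calls. For 600 against 300 °Cd in N+S+ grain it called 28% and 73%, with 4.72% false calls. A gene not called at a single stage may thus have changed by 2-fold or more. These shares of false calls hold for simulated counts only. For low counts, the median chi-square per degree of freedom between real replicates was 2.09 (N-S-, 300 °Cd) to 6.53 (N-S-, 500 °Cd). With N+S- and N+S+ libraries of 600 °Cd exchanged, up to 24 genes were called, against 41 in the real division. Such mixed divisions can keep part of a real difference, so the share of false calls in the real libraries was not measured.

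The comparisons, tests, rule for named genes and gene lists were fixed before the data were examined, and so were these alternatives: DESeq2 size factors in edgeR, DESeq2 1.42.0, no expression filter, a fit to the compared groups alone, the replicate number as a block, each replicate left out, stage 500 left out of the average with its libraries still in the fit, and an additive model with a lane term. Alternatives added after the data had been seen were all genes shared by the compared tables, the authors' library sizes, the third N-S- library at 500 °Cd on its own, scaling without the 20 most abundant genes, every library thinned to the shallowest, the libraries of stage 500 left out of the fit, and lists of 10 or 50 abundant genes.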

Results

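Polyadenylated RNA was sequenced from whole grain of einkorn, Triticum monococcum, a diploid wheat, to ask how nitrogen (N) and sulfur (S) supply after flowering changes gene expression while the grain fills. Time was counted in degree days (°Cd, accumulated temperature) after anthesis, the opening of the flower. Grain came from 6 stages, 100, 200, 300, 400, 500 and 600 °Cd, and from 4 nutrient solutions given from 200 to 700 °Cd. Plants called N-S- received neither element, N+S- plants 6 mM N without S, N-S+ plants 0.5 mM N with 2 mM S, and N+S+ plants 6 mM N with 2 mM S. The stages 100 and 200 carried only the N-S- label, so the 54 libraries formed 18 groups of 3 biological replicates. The 2 complete tables held 1344965 to 5356417 counts per library. All treatment comparisons used the 8649 genes present in every table as used here, which held 370241 to 1736179 counts per library and 22.0% to 33.1% of the counts of a complete table, and 4001 of them passed the expression filter. The files pair no gene identifier with a name or a description, so genes are given by identifier alone.

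Grain age separated the libraries far more than nutrition did. Component 1 of log2 CPM (counts scaled to a common library size) held 40.4% of the variance and component 2 held 13.4%. Each of the 54 libraries had its closest other library in its own stage, and 31 of the 54 in their own group. The 20 most abundant of the shared genes, a list drawn up after the data had been seen, took 6.41% ± 0.48 (SD, n = 3) of the shared-gene counts at 100 °Cd, 25.0% ± 2.24 (SD, n = 3) at 200 °Cd and 49.0% ± 3.00 (SD, n = 3) at 300 °Cd in N-S- grain. The 3 libraries of N-S- grain at 500 °Cd stood apart by a correlation between replicates, across genes, of 0.847 to 0.862, against at least 0.895 in the other groups. They had 3295 to 3660 genes detected, and every other library had at least 3683. With every library thinned to the shallowest they had 3257 to 3590. That range overlapped N+S+ grain at 600 °Cd (3448 to 3801) and N-S+ grain at 500 °Cd (3531 to 3921).

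**Figure D1:**
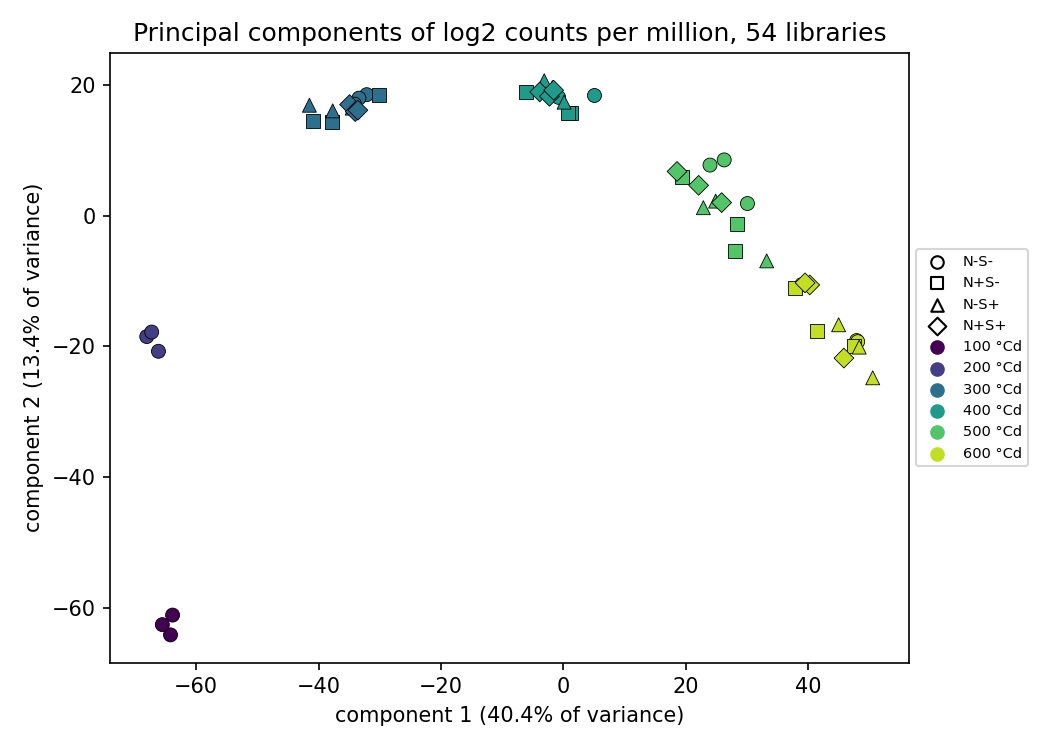
Component 1 (40.4% of the variance) against component 2 (13.4%) of log2 CPM for the 54 libraries, colour by stage in °Cd after anthesis and marker by treatment. Libraries lie by stage along both axes, and the 4 treatments overlap within a stage.

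Grain grown with N but without S differed from fully supplied grain in 88 of 4001 genes, most of them by less than 2-fold and a few by large factors. The highest rise belonged to TmLoc010460, at 173.6 ± 36.2 normalized CPM (mean over 4 stages, SD within stages, 12 libraries) in N+S- against 8.56 ± 6.10 in N+S+ grain. TmLoc001563 fell to 4079 ± 1325 against 35622 ± 11864 CPM. In N+S- grain TmLoc010460 was 19.9-fold higher (log2 fold change 4.32 ± 0.25 SE, adjusted p = 4.85e-22, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and all 3 libraries lay above all 3 N+S+ libraries at each of the 4 stages. TmLoc001563 was 10.3-fold lower (log2 fold change -3.37 ± 0.16, edgeR adjusted p = 1.38e-25), again with no overlap between the groups at any of the 4 stages. Averaged over 300 to 600 °Cd, 45 genes were higher and 43 lower in N+S- than in N+S+ grain, and 28 of the 88 changed by at least 2-fold. The median absolute log2 fold change was 0.70, also with the 2 genes that have a group without counts set at their bounds.

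The other 2 genes with the largest fitted changes had groups without counts, so their fitted changes are no bounds. TmLoc005103 was higher in N+S- grain (edgeR adjusted p = 0.0187), with 33, 13, 13 and 6 counts over 3 libraries in order of stage against 10, 1, 1 and none, and 9 of 12 libraries above the N+S+ mean of their stage. TmLoc005329 was lower (edgeR adjusted p = 0.00289), in 10 of 12 libraries. It had no count in N+S- grain at 300 and 400 °Cd against 42 and 46 in N+S+ grain, at least 13.8-fold and 13.4-fold lower against a floor of 3 counts over the group. At 600 °Cd its levels were 246 and 267 CPM. At 500 °Cd the S-free and S-supplied libraries were on different sequencing lanes, and over the other 3 stages, each within a lane, 56 genes passed the test, 25 higher and 31 lower. In that average, whose estimate of the spread still includes the libraries of 500 °Cd, TmLoc005103 lost its call (fitted log2 fold change 3.19 ± 0.98, edgeR adjusted p = 0.0992, from 3.24 ± 0.85). With those libraries left out of the fit as well 69 genes passed, and with replicate 1 or 3 left out of every group 58 or 39 genes.

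**Figure D2:**
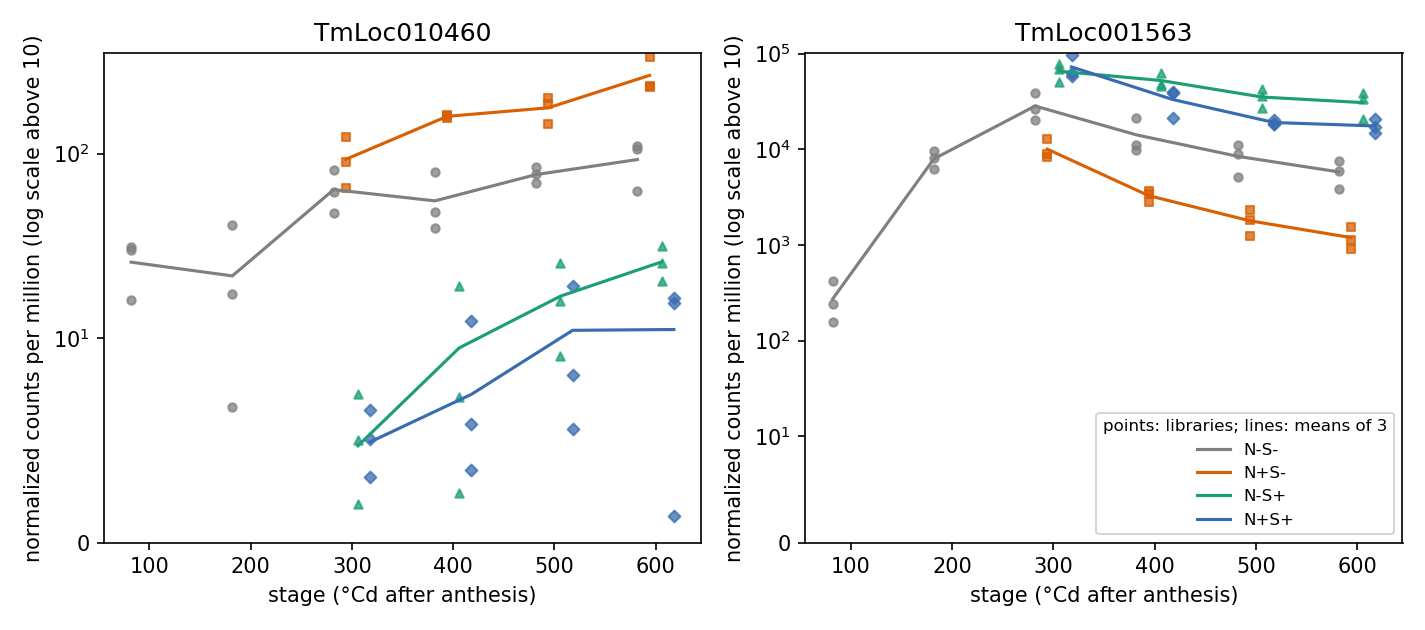
Normalized CPM of TmLoc010460 and TmLoc001563 against stage (°Cd after anthesis), linear below 10 and logarithmic above; points are libraries and lines join means of 3. TmLoc010460 lies higher and TmLoc001563 lower in N+S- than in N+S+ grain at each of the 4 stages, with N-S- grain in between.

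Some of the most abundant transcripts among the shared genes fell. Of the 20 most abundant shared genes, chosen after the data had been seen, 8 were lower and 2 higher in N+S- than in N+S+ grain (9 lower and 3 higher adjusted over the list alone). TmLoc001192, with the highest mean share over all libraries, took 3.34% ± 0.51 (SD, n = 3) of the shared-gene counts in N+S- grain at 600 °Cd and 14.4% ± 2.01 (SD, n = 3) in N+S+ grain. Over the 4 stages it was lower in N+S- grain by a log2 fold change of -2.23 ± 0.13 (edgeR adjusted p = 2.18e-22), in 12 of 12 libraries. TmLoc001996, also among the 20, was lower by a log2 fold change of -2.77 ± 0.14 (edgeR adjusted p = 7.86e-25), in 12 of 12 libraries.

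TmLoc012286, with the next highest mean share, did not share this fall. It took 31.9% ± 5.62 (SD, n = 3) of the shared-gene counts in N+S- grain at 600 °Cd and 15.7% ± 2.09 (SD, n = 3) in N+S+ grain, more than TmLoc001192 in both. Averaged over the 4 stages its share was 7.14 percentage points higher in N+S- grain (exact permutation p = 6.25e-05). Shares sum to a whole, so this rise can in part follow from the fall of other genes, such as TmLoc001192 (-11.4 points). The fitted change of TmLoc012286 was a log2 fold change of 0.35 ± 0.14, with 8 of 12 libraries in that direction. It did not pass the test over all genes (edgeR adjusted p = 0.304). It passed when adjusted over the list alone (edgeR adjusted p = 0.0305). The 20 genes together held 47.6% of the shared-gene counts in N+S- and 60.8% in N+S+ grain, averaged over the 4 stages. That difference, -13.2 percentage points, had p = 1.25e-05 in a two-sided exact permutation test within stages (160000 arrangements), the smallest p the test can give. It was -13.3 points without 500 °Cd. Between N-S- and N-S+ grain the shares were 52.7% and 60.8%, a difference of -8.06 points with p = 1.25e-05 in the same exact test. The share in N+S- grain was on average 5.14 points below that in N-S- grain (exact permutation p = 0.00266), with the widest gap at 400 °Cd (44.8% against 56.4%) and no fall at 600 °Cd (54.7% against 54.6%). N+S+ and N-S+ grain differed by 0.026 points (exact permutation p = 0.981). Adjusted over these 4 comparisons by Benjamini-Hochberg, the values are in the same order 2.5e-05, 2.5e-05, 0.00355 and 0.981.

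**Figure D3:**
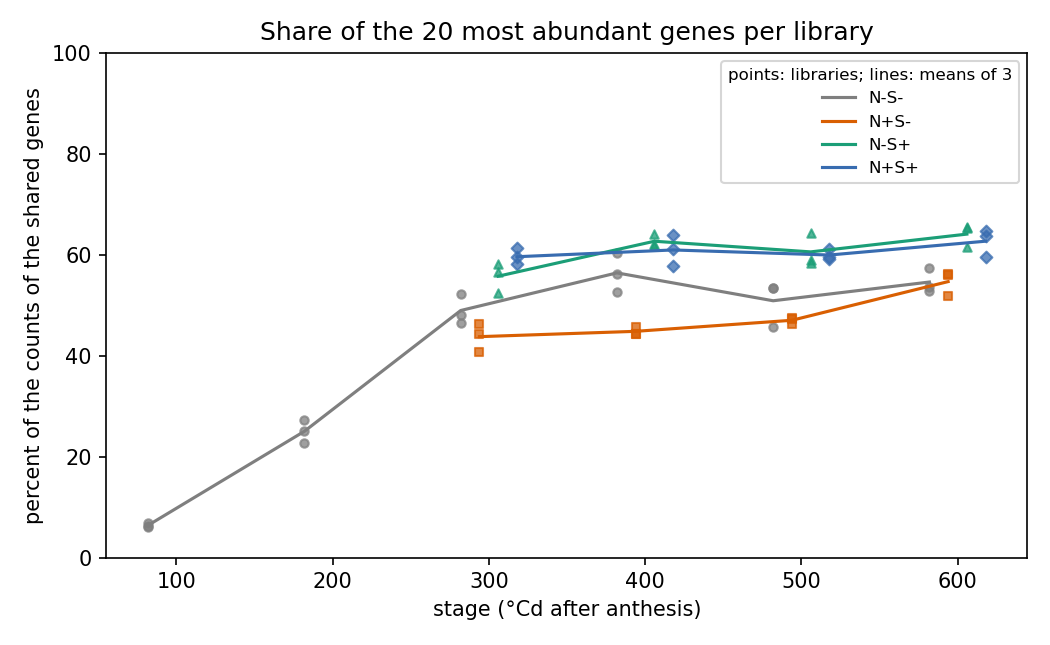
Percent of the shared-gene counts held by the 20 most abundant shared genes, per library (points) and as means of 3 (lines), against stage in °Cd after anthesis. Averaged over 300 to 600 °Cd the share was 47.6% in N+S-, 52.7% in N-S-, 60.8% in N-S+ and 60.8% in N+S+ grain.

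Stage by stage, some of the abundant genes were lower in N+S- grain from the earliest treated stage on. Of the 20, 3 were lower at 300 °Cd, 5 at 400, 6 at 500 and 8 at 600, and none passed the test in the other direction at any of these stages (edgeR; 0, 1, 2 and 2 genes adjusted over the list alone). The fitted change was positive at all 4 stages in 4 of the 20, among them TmLoc012286 and TmLoc003295. Over all 4001 genes, 7 were higher and 4 lower at 300 °Cd, 11 and 20 at 400, 10 and 17 at 500, and 23 and 18 at 600. No gene's response at a single stage differed from the mean of the other 3 stages by edgeR after adjustment. From 136 to 354 genes had an unadjusted p under 0.05, which a share of 0.05 of the 4001 genes would reach by chance. The counts rest on single libraries in places: 7, 7 or 6 genes passed at 300 °Cd without N+S+ replicate 1, 2 or 3, 13 at 400 °Cd without N+S- replicate 3, and 23 or 22 at 600 °Cd without N+S- replicate 1 or 3. Fitted with the spread of the compared groups alone, 30 genes were higher and 12 lower at 300 °Cd, 15 and 32 at 400, 24 and 24 at 500, and 10 and 13 at 600 °Cd. With DESeq2 size factors in edgeR 21 genes were higher and 21 lower at 600 °Cd, and with every library thinned to the shallowest 5 and 6 at 300 °Cd and 13 and 14 at 600 °Cd.

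At low N, grain without S again had more TmLoc010460 and less TmLoc001563, by smaller factors. TmLoc010460 was 5.89-fold higher in N-S- than in N-S+ grain (log2 fold change 2.56 ± 0.25, edgeR adjusted p = 8.84e-12), at 72.2 ± 19.1 against 14.2 ± 6.71 CPM and with no overlap at any of the 4 stages. TmLoc002055 was 2.09-fold higher (log2 fold change 1.06 ± 0.13, edgeR adjusted p = 1.47e-08), in 12 of 12 libraries. Of the 20 most abundant genes, 4 were lower and 2 higher (5 and 3 adjusted over the list alone), among them TmLoc001563 at -1.89 ± 0.15 on the log2 scale (edgeR adjusted p = 1.06e-14). In all, 12 genes were higher and 11 lower in N-S- grain over the 4 stages. This comparison also carried a difference in N, since N-S- plants received none and N-S+ plants 0.5 mM.

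Calls at high and low N overlapped. Of the genes higher without S, 9 were called at both N levels (0.135 expected of independent lists), and of the genes lower without S, 5 were (0.118 expected), with 0 called in opposite directions. The comparisons share no library, but they share the estimate of the spread. At 500 °Cd both set S-free libraries on the second lane against S-supplied ones on the third. A lane difference could thus add calls and signs in common, and the overlap without 500 °Cd was not tested. Of the 88 genes called at high N, 80 had the same sign at low N, against 54.2% of all tested genes, and 87 of the 88 had the larger change at high N, where they had been selected. The genes with the steepest fitted falls by the naming rule, TmLoc004570 and TmLoc005810, were lower in 11 of 12 libraries each (edgeR adjusted p = 0.0376 and 0.0222). At 500 °Cd they had no count in N-S- grain against 20 and 18 in N-S+ grain, at least 5.22-fold and 4.59-fold lower. Both lost their calls without that stage, where the fitted log2 fold changes were smaller, -0.77 ± 0.44 and -0.82 ± 0.42 (edgeR adjusted p = 0.862 and 0.780) from -2.11 ± 0.53 and -2.10 ± 0.50. Without 500 °Cd 9 genes passed in all, and without N-S+ replicate 3 at 500 °Cd 45 genes passed. With replicate 1 or 2 left out of every group 14 passed each time.

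With a spread shared by all 54 libraries, N-S- grain at 500 °Cd gave the most calls of any stage in both treatment comparisons it entered. At that stage 86 genes were lower and 17 higher in N-S- than in N-S+ grain, and 119 genes were higher and 53 lower in N+S- than in N-S- grain. With DESeq2 size factors in edgeR these were 54 lower and 22 higher, and 91 higher and 75 lower, and DESeq2 called 103 lower and 56 higher, and 123 of 224 higher. With the spread of the 2 groups alone 54, 4, 2 and 5 genes passed in the S comparison in order of stage, and 1, 21, 6 and 32 in the N comparison. The 3 N-S- libraries at 500 °Cd are those with the lowest correlation between replicates and, before thinning, the fewest detected genes. The N-S- and N+S- libraries at 500 °Cd shared a lane, and the N-S- and N-S+ libraries did not. Leaving out single libraries moved the S comparison to 35 or 57 genes (N-S+ replicate 1 or 2) and to 65 or 162 (N-S- replicate 1 or 3), and the N comparison to 98 or 90 (N+S- replicate 1 or 3) and to 265 (N-S- replicate 3).

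With S supplied, raising N from 0.5 to 6 mM changed few genes. TmLoc010344 was 1.95-fold higher in N+S+ than in N-S+ grain (log2 fold change 0.96 ± 0.21, edgeR adjusted p = 0.0240), in 11 of 12 libraries, and TmLoc010768 was 1.79-fold higher (0.84 ± 0.19, edgeR adjusted p = 0.0240), in 12 of 12. TmLoc000637 was 1.55-fold lower (-0.63 ± 0.12, edgeR adjusted p = 0.00347), in 11 of 12, at 168.9 ± 38.0 against 257.3 ± 48.3 CPM. Of the 4001 genes, 8 were higher and 1 lower, and of the 20 most abundant genes 1 was higher (4 higher and 2 lower adjusted over the list alone). Single libraries decided this count, which was 5 or 4 without N+S+ replicate 1 or 3 at 300 °Cd, 4 without N+S+ replicate 3 at 400, 5 or 2 without N+S+ replicate 2 or 3 at 500, and 5, 2 or 24 without N+S+ replicate 1, 2 or 3 at 600 °Cd. It was 4, 3 and 15 without N-S+ replicate 2 at 300, 400 and 500 °Cd, and 5, 3 or 17 without N-S+ replicate 1, 2 or 3 at 600 °Cd. DESeq2 called 46 genes, of which 31 were higher, and 0 passed without 500 °Cd (edgeR, 331 at an unadjusted p under 0.05). All 3 named genes lost their calls without 500 °Cd, where the log2 fold changes were smaller and their errors wider, 0.82 ± 0.25, 0.78 ± 0.22 and -0.56 ± 0.14 (edgeR adjusted p = 0.295, 0.295 and 0.119). With the libraries of 500 °Cd left out of the fit as well 6 genes passed.

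Without S, plants given 6 mM N were compared with plants given none, and 98 genes differed. TmLoc001563 was 4.09-fold lower in N+S- than in N-S- grain (log2 fold change -2.03 ± 0.15, edgeR adjusted p = 6.85e-16) and TmLoc001996 was 3.27-fold lower (-1.71 ± 0.13, edgeR adjusted p = 1.84e-15), each in 12 of 12 libraries and at each stage without overlap. TmLoc010712 was higher in 12 of 12 libraries (edgeR adjusted p = 0.000373), with no count in N-S- grain at 500 °Cd against 32 in N+S- grain, at least 9.28-fold higher. TmLoc010469 was higher in 11 of 12 (edgeR adjusted p = 0.00162), with no count against 27 at 500 °Cd, at least 7.88-fold higher, but 115 against 129 at 300 °Cd and 20 against 24 at 400 °Cd. Of the 20 most abundant genes 8 were lower and 1 higher (9 and 3 adjusted over the list alone). Over the 4 stages 62 of the 98 genes were higher and 36 lower. With replicate 1 or 3 left out of every group 48 or 38 genes passed, and with any single library left out 74 to 119. Without 500 °Cd the count was 33, with 17 higher and 16 lower, and with the libraries of that stage left out of the fit as well 39. TmLoc010712 and TmLoc010469 lost their calls without 500 °Cd, where the fitted log2 fold changes were smaller, 2.22 ± 0.62 and 0.80 ± 0.38 (edgeR adjusted p = 0.0683 and 0.624) from 3.40 ± 0.65 and 2.28 ± 0.48.

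The change without S differed between high and low N in 16 genes, and 6 of these belonged to the 20 most abundant. At low N the plants without S received no N and those with S 0.5 mM, so this difference is not one of S alone. In all 6 abundant genes the change without S was more negative at high N, as in TmLoc001563 (difference of log2 fold changes -1.48 ± 0.21, edgeR adjusted p = 2.44e-06) and TmLoc001192 (-1.42 ± 0.17, edgeR adjusted p = 3.38e-08). TmLoc010460 rose more at high N (1.76 ± 0.39, edgeR adjusted p = 0.00811). This interaction was negative in 11 genes and positive in 5. Without 500 °Cd 7 genes were called, all among the 16, and 4 of them were abundant genes. TmLoc010460 was not among the 7, with a similar difference and a wider error (1.73 ± 0.46, edgeR adjusted p = 0.121). With the libraries of 500 °Cd left out of the fit as well 8 genes were called, and with replicate 1 or 2 left out of every group 10 or 7.

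In the fit to all libraries, more genes changed between successive stages than between nutrient solutions. In N-S- grain 552 genes rose and 274 fell from 100 to 200 °Cd, 423 rose and 335 fell from 200 to 300, 196 rose and 154 fell from 300 to 400, 87 rose and 204 fell from 400 to 500, and 341 rose and 255 fell from 500 to 600 °Cd (edgeR, of 4001 tested). The nutrient solutions began at 200 °Cd, so the steps from there on also span growth without N and S. Of the 20 most abundant genes, 17 rose from 100 to 200 °Cd and 15 from 200 to 300 °Cd, and none fell in either step. Among the 1782 genes called in any step, the highest group mean lay at 100 °Cd for 416, at 200 for 246, at 300 for 332, at 400 for 164, at 500 for 174 and at 600 for 450. Directions also turned, with 356 of the 1782 genes rising in some step and falling in another. Both steps that include 500 °Cd depended on the spread estimate, with 21 genes higher and 15 lower, and 50 higher and 65 lower, from the spread of the compared groups alone. With the compared groups alone 600 genes rose and 553 fell from 100 to 200 °Cd, and 598 rose and 642 fell from 200 to 300. With DESeq2 size factors in edgeR 373 rose and 419 fell from 200 to 300 °Cd, 118 and 172 from 400 to 500, and 286 and 300 from 500 to 600, and with the authors' library sizes 177 rose and 180 fell from 300 to 400 °Cd. Without N-S- replicate 1 or 2 at 400 °Cd the 400 to 500 step had 156 or 175 genes in all, and without N-S- replicate 1 or 3 at 600 °Cd the last step had 331 or 367. The 300 to 400 and 500 to 600 steps crossed sequencing lanes.

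**Figure D4:**
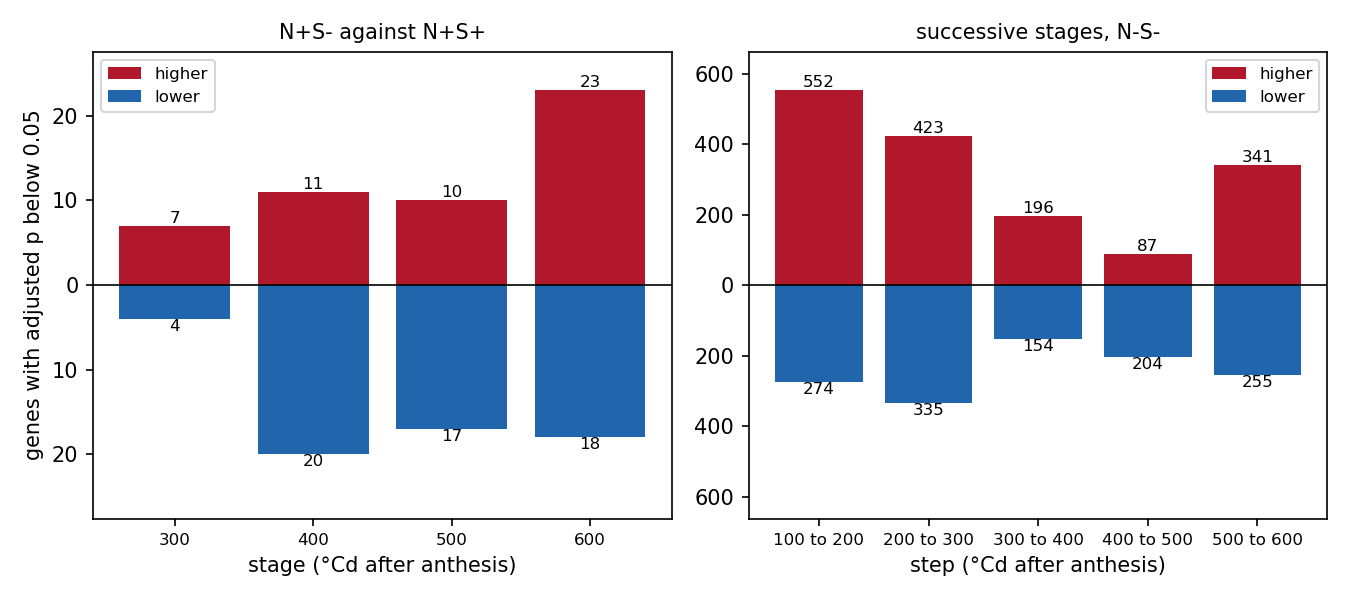
Genes past an adjusted p of 0.05 (edgeR, 4001 tested), higher above and lower below the zero line, for N+S- against N+S+ grain at each stage and for each step between successive stages of N-S- grain (°Cd after anthesis). Counts per stage run from 11 to 41 for the treatment comparison and from 291 to 826 for the steps.

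From 300 to 600 °Cd, genes switched on and off in every treatment. In N+S+ grain TmLoc006533 and TmLoc002057 had no count at 300 °Cd and 279 and 277 counts over 3 libraries at 600 °Cd, at least 116-fold and 114-fold higher against a floor of 3 counts over the group. TmLoc005381 and TmLoc012374 went from 1970 and 1616 counts to none, at least 527-fold and 433-fold lower. In N-S- grain TmLoc011634 and TmLoc007952 had no count at 300 °Cd and were at least 508-fold and 173-fold higher at 600 °Cd. TmLoc005381 was at least 546-fold and TmLoc002360 at least 125-fold lower. Floors cover counting error only.

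Most genes that changed from 300 to 600 °Cd moved the same way under each nutrient solution: of 2370 called in any treatment, 2133 had the same sign in all 4. In N-S- grain 724 genes rose and 844 fell, in N+S- grain 742 and 857, in N-S+ grain 797 and 997, and in N+S+ grain 673 and 839. Of these genes, 470 rose and 535 fell in all 4 treatments, against 4.50 and 9.45 expected of independent lists, and 2 of the 2370 were called in opposite directions. Among the 20 most abundant genes, 9 rose and 10 fell in N+S- grain, and 9 rose and 6 fell in N+S+ grain. The 2 stages ran on different lanes in every treatment, so stage and lane cannot be told apart here. All 4 treatments share this lane difference and the estimate of the spread, which can add calls and signs in common. The share of same signs over all tested genes is not given here.

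The course of development itself differed between N+S- and N+S+ grain in 4 of 4001 genes, a count for which chance cannot be excluded. The 300 to 600 °Cd change was more positive in N+S- grain for 3 genes, with the largest differences in TmLoc006460 (4.11 ± 0.88 on the log2 scale, edgeR adjusted p = 0.0323) and TmLoc010768 (2.26 ± 0.49, edgeR adjusted p = 0.0323). It was more negative for TmLoc004457 (-1.30 ± 0.30, edgeR adjusted p = 0.0494). These genes were named after their values were seen. The count rested on single libraries: it was 1, 0 or 1 without N+S+ replicate 1, 2 or 3 at 300 °Cd, 0, 0 or 2 without N+S- replicate 1, 2 or 3 there, 0 or 1 without N+S+ replicate 2 or 3 at 600 °Cd, and 0 without N+S- replicate 3 at 600 °Cd. By edgeR with all libraries 303 genes had an unadjusted p under 0.05, and DESeq2 called 8.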

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

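The tests of lane, depth, library complexity, scaling and spread in this part were chosen after the result was seen, although the average without 500 °Cd that 2 of them use was itself set earlier, as was the test of later development. A difference between groups or stages, tested itself in edgeR with Benjamini-Hochberg adjustment, singled out each result here. The change without S differed between high and low N in 16 genes over the 4 stages, and the low-N arms also differed in N. The change from 300 to 600 °Cd differed between N+S- and N+S+ grain in 4 genes, among them TmLoc000101 (1.27 ± 0.28 on the log2 scale). In the comparison of N-S- with N-S+ grain, 14 genes responded differently at 500 °Cd than at the other 3 stages, all 14 toward lower values in N-S- grain, and 1 gene did at 400 °Cd, TmLoc007836 (fitted difference in log2 fold change 6.17 ± 1.26). This gene had 20 counts in N-S- against 1 in N-S+ grain at 400 °Cd and none in N-S- grain at 500 °Cd, so the fitted size is no bound. In N+S+ against N-S+ grain 3 genes differed at 600 °Cd: TmLoc010147 (1.55 ± 0.32), TmLoc002655 (1.38 ± 0.28) and TmLoc006517 (1.30 ± 0.28). In N+S- against N-S- grain 20 genes differed at 500 °Cd, 15 upward and 5 downward, 1 at 300 °Cd, TmLoc001192 (1.35 ± 0.28), and 1 at 600 °Cd, TmLoc010933 (-2.22 ± 0.44). The genes named here were chosen after their values were seen.

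Many genes were called at 500 °Cd in the comparisons with N-S- grain, given the spread shared by all libraries. Sequencing lane cannot account for the calls against N+S- grain, since 172 genes were called within a lane and 103 in the comparison between lanes. Lower depth cannot either, since with every library thinned to the shallowest 64 genes were called there, against 21 at the highest of the other stages. Low complexity of the 3 libraries remains a candidate explanation. Their chi-square per degree of freedom between replicates was 6.53 for genes of 10 to 50 expected counts. The next highest group, N-S- grain at 100 °Cd, had 5.10 with 4457 to 4746 genes detected. This measure thus reflects spread between replicates of any origin and cannot single out complexity. With the spread of the compared groups alone 6 genes passed against N+S- and 2 against N-S+ grain, so both counts depend on the shared spread. For the 103 genes called against N-S+ grain, lane and S supply cannot be told apart, because the arms share 0 lanes at this stage, and depth stays open, with 7 genes called after thinning against 5 at the highest of the other stages.

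The abundant shared genes that fell in N+S- against N+S+ grain had a median log2 fold change of -1.53. With the 20 most abundant genes left out of the scaling the median was -1.54. TMM already trims genes of extreme abundance, so leaving these out could hardly move it. That value therefore cannot decide on scaling by a few dominant genes. Lane is argued against by a median of -1.42 over the 3 stages run within a lane. For later development of N+S- grain a slope of at least 0.1 of the S effect on the stage change in N-S+ grain had been set. The slope was 0.0107 (95% interval -3.19e-05 to 0.0210, 1794 genes), which argues against it only as far as these libraries go. The interval came from resampled genes, so it leaves out the variation between libraries, and the stage change also crossed lanes. In N-S+ grain the abundant genes that fell had a median log2 fold change of 0.65 from 300 to 600 °Cd, a rise. Not all of them rose, since TmLoc001563 went from 65610 to 30798 CPM. No criterion was set for slower development of N+S- grain, which was not tested. As a hypothesis found and tested on the same data, a lack of S with N in supply may lower these transcripts. The fall was not confined to high N: 4 of the 20 most abundant genes were also lower in N-S- than in N-S+ grain, which differed in N as well.

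N supply changed more genes without S than with S. The spread of the N-S- libraries at 500 °Cd is excluded as the whole cause, since 7 genes were called for the interaction of N and S over 300, 400 and 600 °Cd, and 8 with the libraries of 500 °Cd left out of the fit as well. The size of the N step remains open and untested, because plants without S went from 0 to 6 mM N and plants with S from 0.5 to 6 mM.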

How the results depend on the processing

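The alternatives with all genes of the compared tables, the authors' library sizes, the third N-S- library at 500 °Cd alone, scaling without the 20 most abundant genes, thinned libraries, the libraries of 500 °Cd left out of the fit and lists of 10 or 50 abundant genes were chosen after the data had been seen. No called change of a named gene and no called difference in share changed sign under any alternative, and the uncalled difference in share between N+S+ and N-S+ grain did in 2 of 6. The majority of calls, higher or lower, turned in 29 of 205 counts, among them N+S- against N+S+ at 600 °Cd (10 higher and 13 lower with the compared groups alone), the 200 to 300 °Cd step (373 and 419 with DESeq2 size factors in edgeR) and the 300 to 400 °Cd step (177 and 180 with the authors' library sizes), and in 27 of 309 counts with libraries left out. Not counting libraries left out, 149 of 217 counts and shares that answer a comparison stayed within 1.5 times their main value or within the spread between replicates, and 409 of 445 values of single named genes stayed on their side of the threshold, with 32 weaker and 4 stronger. DESeq2 size factors in edgeR, the authors' library sizes and scaling without the 20 most abundant genes moved none of these past that range or threshold, and size factors shifted the median log2 fold change of all genes by -0.0885 from 200 to 300 °Cd, by 0.0733 for N-S- against N-S+ at 500 °Cd and by less in each of the other comparisons. Libraries of 400 °Cd held 370241 to 641733 counts. With every library thinned to the shallowest, which lowers depth by construction, N+S+ against N-S+ had 1 gene, N+S- against N-S- 57 on average and 64 at 500 °Cd, N-S- against N-S+ 7 at 500 °Cd, N+S- against N+S+ 27 at 600 °Cd, the difference of the 300 to 600 °Cd change 1, and 4 steps of N-S- grain 524 from 100, 488 from 200, 160 from 400 and 287 from 500 °Cd. The pseudocount alternative was not run because the tables hold counts, and the tests of gene lists were not run because no gene names were at hand. For each value below the cause was not tested unless one is given.

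With all genes of the compared tables more genes were tested, which raises counts by construction: N+S- against N+S+ had 217 on average and, from the earliest of the 4 stages to the latest, 27, 95, 73 and 103, N+S- against N-S- 389 at 500 °Cd and 223 on average, the difference of the 300 to 600 °Cd change 27, the 5 steps of N-S- grain 3673, 3462, 1573, 1316 and 2359, and 600 against 300 °Cd 6430 in N+S+, 3612 in N+S- and 6671 in N-S- grain. Without the expression filter the interaction had 37 genes, N+S+ against N-S+ 46, N+S- against N+S+ 25, 55 and 41 at 300, 400 and 500 °Cd, N-S- against N-S+ 47 and the difference of the 300 to 600 °Cd change 25. DESeq2 called 46 genes for N+S+ against N-S+, 19 and 51 for N+S- against N+S+ at 300 and 400 °Cd, 159 and 44 for N-S- against N-S+ at 500 °Cd and on average, and 8 for the difference of the 300 to 600 °Cd change.

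With the compared groups alone 20 genes passed for N+S+ against N-S+, 42, 47, 48 and 23 for N+S- against N+S+ in order of stage, 6 for N+S- against N-S- and 2 for N-S- against N-S+ at 500 °Cd, and 1240, 528, 36 and 115 for the steps from 200 °Cd on. The additive model with lane gave 2 genes for N+S+ against N-S+, 63 for N+S- against N-S-, 47 for N+S- against N+S+ and 10 for N-S- against N-S+. With 500 °Cd left out of the average and its libraries still in the spread, fewer samples by construction, these were 0 (edgeR, 331 at an unadjusted p under 0.05; DESeq2 with 500 °Cd called 46), 33, 56 and 9, and the interaction had 7. With those libraries left out of the fit as well the interaction had 8 genes, N+S- against N-S- 39, N-S- against N-S+ 9 and N+S- against N+S+ 56 at 400 °Cd. With the third N-S- library at 500 °Cd alone, assumed to vary like the other groups, N+S- against N-S- had 149 genes, N-S- against N-S+ 39 on average and 51 at 500 °Cd, and the 500 to 600 °Cd step 194. With the replicate number as a block N+S+ against N-S+ had 14.

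Leaving out single replicates or libraries, 241 of 321 such values stayed as close. The ranges, fewest to most genes, were 7 to 20 for the interaction, 0 to 24 for N+S+ against N-S+, 38 to 119 for N+S- against N-S- and 47 to 265 at 500 °Cd, and 14 to 45 for N-S- against N-S+ and 11 to 162 at 500 °Cd. For N+S- against N+S+ they were 39 to 97 on average and 6 to 11, 13 to 28, 16 to 26 and 15 to 49 in order of stage. The difference of the 300 to 600 °Cd change had 0 to 6, the steps of N-S- grain 547 to 733, 457 to 642, 194 to 284, 132 to 308 and 199 to 706, and 600 against 300 °Cd 998 to 1433 in N+S+, 1126 to 1469 in N+S-, 1401 to 1644 in N-S+ and 1072 to 1473 in N-S- grain. Differences in the share of the 20 most abundant genes, in percentage points, ran from -13.9 to -12.8 for N+S- against N+S+, from -8.67 to -7.42 for N-S- against N-S+, from -6.99 to -3.81 for N+S- against N-S- and from -0.534 to 1.08 for N+S+ against N-S+.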

Other observations

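Every test of other divisions of the libraries in this part was set before its result was seen, and the genes named here were chosen after their values were seen. Abundant genes followed different courses in time. In N-S- grain TmLoc012286 took 0.030% ± 0.021 (SD, n = 3) of the shared-gene counts at 100 °Cd, 2.34% ± 0.36 at 300 °Cd and 16.1% ± 1.16 at 600 °Cd. TmLoc001563 took 0.059% ± 0.027 at 100 °Cd and 3.13% ± 0.84 at 300 °Cd, and 0.536% ± 0.154 at 600 °Cd. In N+S+ grain TmLoc001563 took 6.31% ± 1.59 at 300 °Cd and 1.32% ± 0.18 at 600 °Cd. TmLoc001192 took 19.8% ± 0.86 at 300 °Cd and 14.4% ± 2.01 at 600 °Cd in N+S+ grain, and 11.6% ± 2.79 and 3.34% ± 0.51 in N+S- grain.

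Libraries were divided anew within their stages, 100 divisions per averaged comparison with the real one included, and genes counted by edgeR. For N+S- against N+S+ the real division gave 88 genes and the highest other 28, and for N-S- against N-S+ 23 and 11. For N+S+ against N-S+ they were 9 and 3, and for N+S- against N-S- 98 and 5. In each, 1 of 100, the real division, gave as many genes, a share under the 0.05 set beforehand. Chance alone is thus unlikely to give these counts, but this does not vouch for single genes. The 9 genes of N+S+ against N-S+ fell to 0 without 500 °Cd. For the interaction the real division gave 16 genes and the highest other 10. Its divisions exchanged S labels and so removed the S effect at both N levels. They cannot say how many genes an equal S effect at both levels would give. For the difference in the 300 to 600 °Cd change between N+S- and N+S+ grain chance cannot be excluded. At least its 4 genes were given by 11 of 100 divisions, and the highest gave 33. Labels were exchanged separately at 300 and 600 °Cd, so a division can turn the S effect itself into a difference between these stages. Such divisions thus cannot decide whether the 4 genes arose by chance.

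For 3 libraries against 3 the 10 divisions are too few for a share under 0.05. The real counts and the highest of the other divisions were, for N+S- against N+S+, 11 and 1 at 300 °Cd, 31 and 2 at 400, 27 and 0 at 500, and 41 and 24 at 600 °Cd. At 500 °Cd they were 103 and 90 for N-S- against N-S+ and 172 and 16 for N+S- against N-S-. For successive steps of N-S- grain they were 826 and 2, 758 and 0, 350 and 0, 291 and 33, and 596 and 102. For 600 against 300 °Cd they were 1568 and 0 in N-S-, 1599 and 3 in N+S-, 1794 and 0 in N-S+, and 1512 and 1 in N+S+ grain.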
